A study of Homo sapiens with 6 samples.

How the data were processed

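The series holds 6 RNA sequencing libraries labelled as the cell line SW480, 3 as DDX39B overexpression and 3 as control, grouped by their titles. Per the labels' protocols, RNA was harvested with an RNeasy kit and sequencing libraries were made with a SMARTer mRNA kit. How DDX39B was overexpressed, whether the libraries came from separate cultures, and whether the kit and the counting kept the strand are not given in the sources used here. The authors deposited a single table of FPKM per gene and library, with gene length. The unit was read from the name of the table and from its values, as the column headers name only the samples. The aligner and the counter are not given in the sources used here. Per the submitters' processing notes the genome build was mm10, a mouse build, whereas all 58735 gene identifiers of the table were human, and all 58735 agreed in identifier, start, end and symbol with the human GENCODE release 29 annotation of GRCh38. Coordinates are those of the table. The table held 0 further columns of values per sample.

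Each FPKM value was multiplied by the gene length and divided by the smallest such product above 0 in its library, taken as 1 read. All values above 0 (100% in each of the 6 libraries) came out whole within 0.001 read. The reads worked out in this way summed to 16963075, 16968725 and 17463697 in the control-labelled and 16980763, 17170008 and 17037195 in the overexpression-labelled libraries. The denominator of the deposited FPKM was 0.961, 0.995 and 0.958 times that sum in the control-labelled and 1.04, 1.05 and 1.05 times in the overexpression-labelled libraries, so the authors' values carry a scaling factor besides the read total. A floor of 3 reads was worth 0.166 to 0.184 FPKM for a gene of 1 kilobase. No pair of libraries held the same values. The chi-square per gene of their reads was 2.19 to 2.56 between overexpression-labelled and 8.08 to 36.9 between control-labelled libraries, above the value of 1 that sampling noise alone gives, so all 6 were kept as separate libraries. The median SD of the log2 values was 0.0592 in the overexpression-labelled and 0.128 in the control-labelled group.

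Because the table holds FPKM and no counts, the main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), two-sided, group as the only term, over genes with a mean of at least 1 FPKM over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low values. Folds given in the text are ratios of mean FPKM. Where a group had 0 reads, the fold was computed against a floor of 3 reads over the group and is a lower bound, and with 1 to 3 reads in a group it has an exact 95% counting interval. Bounds and intervals cover counting error only, and reads from amplified libraries are not independent molecules. Genes with near-identical copies, overlapping genes and antisense genes may share reads, as the counting is not described.

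The 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members (28) were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the 28 lists. The list of leukocyte markers had 0 tested members, and those of fibroblast and endothelial markers 1 each. Adjusted over the list alone, the counts of members past the threshold were those given, except for SR proteins and hnRNPs (3 higher and 10 lower) and NF-kB genes (7 higher and 5 lower). The text could name DDX39B, DDX39A and DCLK1; the 12 protein-coding genes with the largest positive and the 12 with the largest negative log2 fold change past the threshold with groups that did not overlap; and up to 4 members past the threshold per list by size of change, or 2 by expression where none passed. These made 130 genes. Others, such as CDX2, MYC, CD44, DKK1, JUP, BRCA1 and HIST1H2BH, were chosen after their values were seen.

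Alternatives changed the pseudocount (0.1), the filter (none, or a mean of 5 FPKM), the scaling (TPM, median ratio, quantile), the variance model (no trend, array weights), the genes tested (protein-coding), the replicate number as a block, a fold threshold, and each library left out in turn. Chosen after seeing the data were voom on the reads worked out, FPKM recomputed on the sum of reads, and the removal of mitochondrial genes. The same steps were tested on simulated reads for 13057 genes with 200 changed. Of genes changed 2-fold up and down, 96% and 94% were called, and 90% and 84% of those changed 1.5-fold up and down to 0.667-fold, while 8 of 12857 unchanged genes were called. Both simulated groups had the same dispersion between libraries (0.0021). The real groups differed in spread (median SD 0.0592 and 0.128) and in most genes, so these rates may not hold for them. Tables were read with Python and pandas and drawn with matplotlib.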

Results

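RNA sequencing was carried out on 6 libraries that their titles name as SW480, a cell line from a human colorectal adenocarcinoma, in 2 groups. The labels describe 3 libraries as DDX39B overexpression and 3 as control. Gene expression was deposited as FPKM, a value scaled for gene length and library size, for 58735 genes. Multiplying each value by the gene length gave whole numbers of reads, which summed to 16963075 to 17463697 per library, so depth differed little between libraries. The level of DDX39B went against the labels, as described next. The groups are therefore called overexpression-labelled and control-labelled, and every direction below is drawn from the labels as given.

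DDX39B encodes an RNA helicase of the TREX complex, which couples splicing to nuclear mRNA export, and was the gene the labels say was overexpressed. DDX39B (ENSG00000198563, chromosome 6, 31530219 to 31542448, minus strand, GRCh38) was lower, not higher, in the libraries labelled overexpression. It measured 15.02, 13.87 and 14.03 FPKM in those 3 libraries and 39.3, 34.6 and 41.9 FPKM in the control-labelled libraries. The means were 14.3 ± 0.62 and 38.6 ± 3.7 FPKM (SD, n = 3 each), a level 2.70-fold lower under the overexpression label, with a log2 fold change of -1.37 (SE 0.079, limma adjusted p = 6.93e-06). The difference rested on 5368 reads against 13490 reads. The FPKM of a gene does not tell a transgene transcript without the native untranslated regions from the native mRNA, and reads outside the annotated gene model do not enter it.

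DDX39A, the close paralogue of DDX39B, measured 28.4 ± 0.81 FPKM in the overexpression-labelled and 35.98 ± 3.8 FPKM in the control-labelled libraries (SD, n = 3 each). Its log2 fold change was -0.33 (SE 0.083, limma adjusted p = 9.88e-03). That call was lost under 3 other scalings, at -0.22 and an adjusted p of 0.057 when FPKM was recomputed on the sum of the reads, and at -0.19 and 0.0683 after quantile normalization. Without the mitochondrial genes it was -0.23, with an adjusted p of 0.0567. Of 7 tested genes that neighbour DDX39B in the class III region of the major histocompatibility complex, 1 was higher and 5 were lower (camera adjusted p = 0.30). NFKBIL1 was 2.26-fold and GPANK1 2.06-fold lower under the overexpression label. LTB, a cytokine gene, had 353 reads in the overexpression-labelled libraries and 0 in the control-labelled ones, and was at least 110-fold higher.

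DCLK1, a microtubule-associated kinase used as a marker of tuft cells and of tumour stem cells, is named in the title of the series as the transcript that DDX39B stabilizes. As the study that made these samples names it, its difference here is no independent evidence. DCLK1 (ENSG00000133083, chromosome 13, 35768652 to 36131306, minus strand) measured 12.8, 13.2 and 13.3 FPKM in the overexpression-labelled libraries and 0.034, 0.029 and 0.087 FPKM in the control-labelled libraries. The means of 13.1 ± 0.25 and 0.050 ± 0.032 FPKM (SD, n = 3 each) differed 261-fold, with a log2 fold change on the FPKM + 1 scale of 3.75 (SE 0.061, limma adjusted p = 3.52e-08). DCLK1 was thus close to undetected in the control-labelled libraries, with 36 reads in all 3 together against 10081. It was higher in the group in which DDX39B was lower. Among protein-coding genes, 318 others differed by at least as large a fold, 182 of them higher and 136 lower under the overexpression label.

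**Figure D1:**
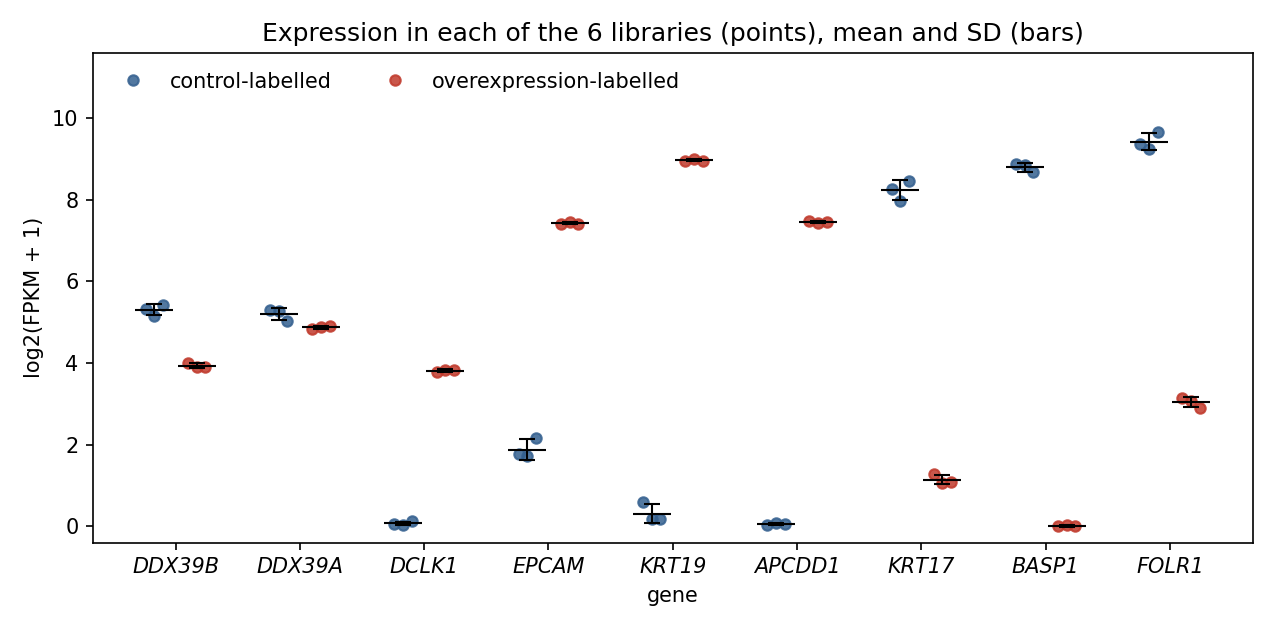
Expression of 9 genes on a log2(FPKM + 1) axis in each of the 6 libraries; points are libraries, horizontal bars are group means and whiskers are SD (n = 3). DDX39B lies lower in the overexpression-labelled libraries (13.9 to 15.0 FPKM) than in the control-labelled ones (34.6 to 41.9 FPKM), and DCLK1, EPCAM, KRT19 and APCDD1 lie higher, while KRT17, BASP1 and FOLR1 lie lower.

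The difference between the groups took in most of the tested genes. Of 13972 genes with a mean of at least 1 FPKM, 10726 (76.8%) passed an adjusted p of 0.05, 5241 higher and 5485 lower under the overexpression label. Of these, 2213 were higher and 2145 lower by a log2 fold change of at least 1. The 2-fold count rose to 7152 of 18899 tested genes after rescaling to TPM. With a pseudocount of 0.1 it rose to 5340 of the 13972 genes. With no filter on low values 15105 of 33913 genes (44.5%) passed. The values of the groups did not overlap for 11193 genes (80.1%), where chance gives 10%. Pearson correlations of log2 values across genes were 0.974 to 0.991 between libraries of a group and 0.676 to 0.685 between libraries of different groups (genes are not independent replicates). The first principal component, which parted the groups, held 94.4% of the variance.

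Genes of cytokeratins, secreted growth factors and receptors made up much of the upper end. Among the 12 protein-coding genes with the largest positive change were the intermediate filament genes KRT5, KRT19, KRT23 and KRT13. KRT5 measured 579 ± 31 FPKM against 0.38 ± 0.18 FPKM, a 1523-fold difference (log2 fold change 8.72, SE 0.098, limma adjusted p = 1.14e-08). KRT19 measured 500 ± 8.0 FPKM against 0.25 ± 0.21 FPKM (1991-fold). APCDD1, an inhibitor and target of Wnt signalling, measured 174 ± 3.6 FPKM against 0.037 ± 0.015 FPKM (4726-fold). FGF3 had 9981 reads in the overexpression-labelled libraries and 0 in the control-labelled ones, so it was at least 3100-fold higher, and FGF19 had 15330 reads against 5. Also at this end were PRF1 (23203 reads against 6), CST1 (9947 reads against 9), NGFR (155 ± 3.2 against 0.49 ± 0.30 FPKM) and SAA1 (230-fold), SAA1 being a gene with a near-identical copy, SAA2, with which it may share reads.

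At the lower end stood genes that were abundant in the control-labelled libraries and far scarcer in the others. BASP1, a membrane-bound signalling protein gene, had 49429 reads in the control-labelled libraries (447 ± 33 FPKM) and 1 read in the overexpression-labelled ones, a 53680-fold difference with a 95% counting interval of 9520 to 2095000. FOLR1, the folate receptor alpha gene, measured 7.25 ± 0.69 FPKM against 690 ± 101.5 FPKM, and was 95.1-fold lower (log2 fold change -6.38, SE 0.12, limma adjusted p = 5.01e-08). KRT17 was 251-fold lower, although it shares sequence with KRT16 and with pseudogenes. The alkaline phosphatase genes ALPL and ALPI were 1959-fold and 1093-fold lower, lipoprotein lipase (LPL) 1821-fold and CPS1, which catalyses the entry step of the urea cycle, 1321-fold. SPINK5 and PRSS21 had 0 reads under the overexpression label and were at least 11940-fold and at least 2843-fold lower. SMOC1, C4BPB and CD55 completed the 12 genes. SMOC1 was 12580-fold lower (95% counting interval 3459 to 103200, from 2 reads) and CD55 135-fold, and C4BPB had 4 reads against 16464. At 10 FPKM or more in a group and 3 reads or fewer in all libraries of the other, 37 protein-coding genes were seen in each direction.

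**Figure D2:**
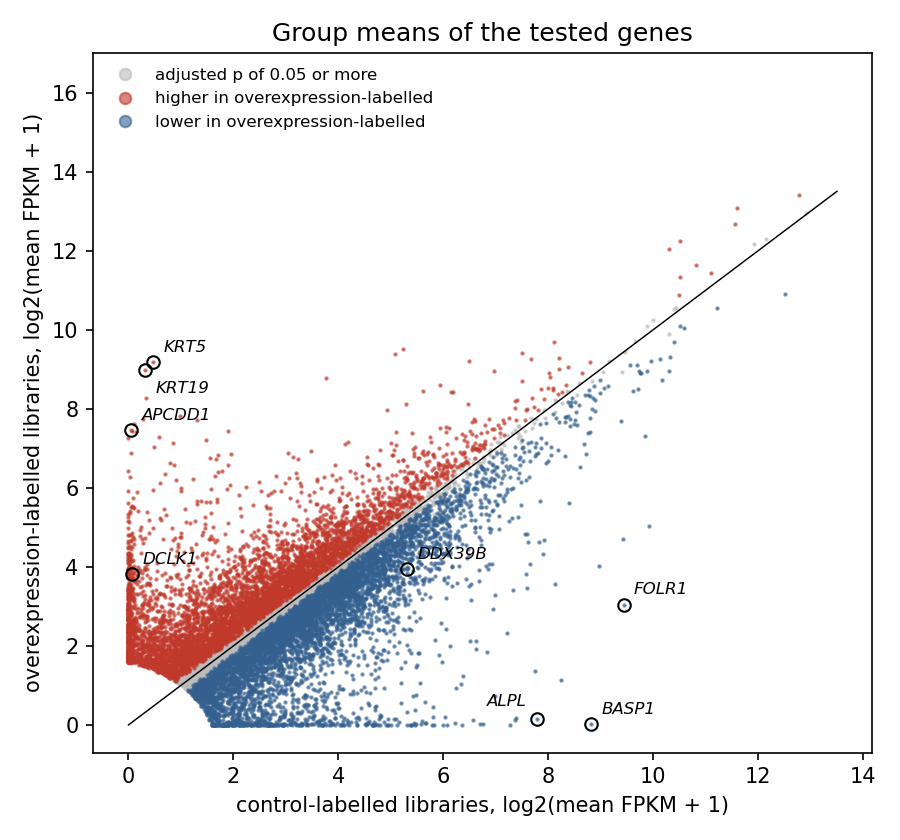
Mean expression of the tested genes in the control-labelled (x axis) and overexpression-labelled libraries (y axis), both as log2(mean FPKM + 1), with the line of equal expression; each point is a gene and open circles mark 8 named genes. Red and blue points are the 5241 genes that were higher and the 5485 that were lower at a limma adjusted p under 0.05, and points along the axes are genes with almost no reads in a group.

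Wnt targets and junction genes of epithelial cells were higher under the overexpression label. Of 21 tested Wnt/beta-catenin targets, 17 were higher and 3 lower (camera adjusted p = 2e-05), with a median log2 fold change of 2.55, or 2.93 with genes at 0 in a group set at their bound. With an estimated correlation between genes the adjusted p was 0.68. SOX9 was 135-fold, AXIN2 48.0-fold and NKD1 179-fold higher, and the stem cell factor ASCL2 was at least 738-fold higher. The 3 lower members were MYC, CD44 and DKK1, a secreted Wnt inhibitor. Of 16 tested epithelial junction genes, 13 were higher and 1, JUP, was lower (camera adjusted p = 1.72e-03; adjusted p = 0.68 with an estimated correlation). EPCAM, an epithelial adhesion molecule, measured 171 ± 3.6 FPKM against 2.72 ± 0.67 FPKM, CDH1, the E-cadherin gene, was 38.7-fold higher, and CLDN3 was 145-fold higher. The splicing regulator gene ESRP1 had 3986 reads against 5, of which 4 were in a single control-labelled library.

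Genes of intestinal differentiation, stem cells and mesenchyme moved in both directions. Of 8 tested enterocyte and goblet cell genes, 5 were higher, among them KRT19 and VIL1 (22.9-fold), and 3 were lower, among them ALPI and ANPEP (174-fold; camera adjusted p = 0.402). CDX2, the intestinal homeobox factor, measured 4.80 ± 0.27 FPKM under the overexpression label and had 0 reads in the 3 control-labelled libraries. The 14 tested stem cell markers were 7 higher, led by SOX9 and EPCAM, and 7 lower, led by CD24 (25.3-fold; camera adjusted p = 0.901), and their median log2 fold change (-0.28) and mean (0.50) differed in sign. Rescaled to TPM, with 16 markers tested, 9 were higher and 7 lower and the median was 0.72. Only 3 tuft cell markers other than DCLK1 were expressed enough to be tested. SOX9 was higher, while PTGS1 was 367-fold lower and ALOX5 270-fold lower (95% counting interval 75.2 to 2261), with a camera adjusted p of 0.729. Of 18 mesenchymal genes, 6 were higher and 11 lower (camera adjusted p = 0.389). MMP14 was higher, with 6399 reads against 9, while COL5A1 was 433-fold lower, TWIST2 18.9-fold lower and TWIST1 at least 238-fold lower.

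Genes of the endoplasmic reticulum and amino acid stress responses were lower under the overexpression label. Of 18 unfolded protein response genes, 16 were lower and 0 higher (camera adjusted p = 4.6e-04; adjusted p = 0.914 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, measured 159 ± 4.4 FPKM against 919 ± 166 FPKM (5.79-fold lower), and XBP1, SDF2L1 and HERPUD1 were 4.95-fold, 4.28-fold and 4.10-fold lower. Of 20 genes of the ATF4 integrated stress response, 16 were lower and 2 higher (camera adjusted p = 1.72e-03; adjusted p = 0.914 with an estimated correlation). NUPR1 was 621-fold, CTH 23.8-fold and DDIT4 18.4-fold lower, whereas ATF5 was 11.7-fold higher. Heat shock genes were 8 lower, 0 higher and 7 not past the threshold (camera adjusted p = 0.104), and some varied widely among the control-labelled libraries. HSPA6 measured 41.5, 19.8 and 160 FPKM there and at most 0.071 FPKM in the others, and its log2 fold change was -5.66 (SE 0.68, limma adjusted p = 2.62e-04). With voom on the reads it was larger, -10.60, at an adjusted p of 0.0682. HSPA1A and HSPA1B, near-identical genes whose reads cannot be parted with certainty, measured 500 ± 350 and 278 ± 172 FPKM in the control-labelled libraries and 15.2 ± 0.61 and 10.9 ± 0.33 FPKM in the others, and CHORDC1 was 8.78-fold lower.

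Cholesterol synthesis genes were 18 higher and 1 lower of 24 (camera adjusted p = 3.91e-03; adjusted p = 0.914 with an estimated correlation). TM7SF2 was 15.9-fold and SQLE, which encodes squalene epoxidase, 3.84-fold higher. Fatty acid synthesis genes moved both ways, 4 higher and 5 lower of 12 (camera adjusted p = 0.901), with ACSS2 2.35-fold higher and ELOVL5 2.84-fold and FADS1 2.65-fold lower. Of the 13 mRNAs of the mitochondrial genome, 8 were higher and 0 lower (camera adjusted p = 0.0142; adjusted p = 0.914 with an estimated correlation). After quantile normalization 9 of them were higher and 4 lower, and the list's camera adjusted p was 0.402. With FPKM recomputed on the sum of reads 12 were higher and 0 lower. MT-CYB was 3.31-fold and MT-ND3 3.34-fold higher, and mitochondrial genes took 6.00% to 6.23% of the reads in the overexpression-labelled and 4.26% to 5.02% in the control-labelled libraries. The share of mitochondrial rRNA went the other way, 0.352% to 0.379% against 0.866% to 1.06%. Histone genes of the replication-dependent clusters were 9 higher and 1, HIST1H2BH, lower among 12 tested (camera adjusted p = 0.0271; adjusted p = 0.914 with an estimated correlation), and the adjusted p was 0.0524 once mitochondrial genes were left out. HIST1H2BK was 4.02-fold and HIST1H2BD 4.34-fold higher, and histone genes are near-identical copies whose reads may be shared. Cytosolic ribosomal protein genes were 6 higher and 18 lower of 30 (camera adjusted p = 0.0807), RPS2 2.01-fold and RPL4 1.94-fold lower.

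Genes of the machinery in which DDX39B acts did not pass the camera test. Of 24 tested TREX and mRNA export genes, 8 were higher and 10 lower (camera adjusted p = 0.901), and their median log2 fold change, -0.01, changed sign with the scaling. PCID2 was 5.44-fold, THOC6 3.42-fold and CHTOP 2.27-fold lower, while NXT1 was 1.82-fold higher. Of 25 genes of the U2 snRNP and early spliceosome, 11 were higher, with SNRNP70 at 2.06-fold, and 11 lower, with PRPF3 at 2.42-fold (camera adjusted p = 0.918). SR proteins and hnRNPs were 4 higher and 10 lower of 24 (camera adjusted p = 0.389), HNRNPU 1.98-fold and CLK2 1.94-fold lower. Among 3 tested transcripts that have been reported to depend on DDX39B (camera adjusted p = 0.918), PKM was 1.48-fold higher and BRCA1 measured 7.97 ± 0.32 against 8.14 ± 0.89 FPKM. By limma's fry, which looks at the genes of a list alone, TREX genes (adjusted p = 5.15e-04), SR proteins and hnRNPs (2.79e-03) and the reported transcripts (0.01) were on balance lower, and U2 genes did not pass (0.0985). The fry test was run at the deposited scaling alone. With FPKM recomputed on the sum of reads, TREX genes were 9 higher and 8 lower (median 0.088). SR proteins and hnRNPs were then 5 higher and 10 lower (median -0.035).

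Proliferation and signalling lists did not pass the set test. G2/M genes were 12 higher and 2 lower of 25 (camera adjusted p = 0.344), AURKA 1.88-fold higher and CDK1 2.07-fold lower. G1/S and DNA replication genes were 6 higher and 11 lower of 25 (camera adjusted p = 0.496), PCNA and MCM7 2.26-fold and 2.13-fold higher and CDT1 3.47-fold lower. Immediate early and ERK target genes were 15 higher and 6 lower of 24, with a camera adjusted p of 0.0552 that ranged from 0.0138 to 0.0986 over the other processing settings with the same preset correlation. DUSP6, a phosphatase induced by ERK, was 326-fold and SPRY4 17.6-fold higher, while DUSP1 was 29.3-fold lower. TGF-beta targets were 8 higher and 6 lower of 16 (camera adjusted p = 0.801), with LTBP2 116-fold higher and ID3 63.0-fold lower. ID2 was higher, at 64.2 ± 2.8 FPKM against 1.73, 1.07 and 8.37 FPKM in the control-labelled libraries. Hypoxia and glycolysis genes were 8 higher and 14 lower of 27 (camera adjusted p = 0.402), the glucose transporter genes SLC2A3 and SLC2A1 143-fold and 7.24-fold higher and VEGFA 8.33-fold and BNIP3 23.5-fold lower. p53 targets were 11 higher and 7 lower of 20 (camera adjusted p = 0.646), with a median of 0.24 and a mean of -0.07, GDF15 being 7.58-fold lower and PHLDA3 3.32-fold higher. Interferon-stimulated genes were 6 higher and 7 lower of 16 (camera adjusted p = 0.923), with OAS2 627-fold higher (95% counting interval 215 to 3053) and BST2 14.5-fold lower. NF-kB and inflammatory genes were 6 higher and 4 lower of 14 (camera adjusted p = 0.659), with CSF2 at least 210-fold and LIF 6.76-fold higher and PTGS2 68.8-fold lower.

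Few markers of other cell types that a culture could hold were expressed enough to be tested. None of the 12 leukocyte markers reached a mean of 1 FPKM, and CD3D and MS4A1 had 0 reads in all 6 libraries. COL1A1 was the only fibroblast marker tested (4.01-fold lower) and ESAM the only endothelial marker (64.2-fold lower). ESAM was not scarce in the control-labelled libraries, at 43.5 ± 7.4 FPKM against 0.68 ± 0.13 FPKM in the others. Of 3 tested genes of embryonic kidney cells, PAX8 was 9.01-fold and LHX1 32.8-fold higher and INA at least 291-fold lower (camera adjusted p = 0.501). PAX8 and LHX1 measured 6.27 and 5.92 FPKM in the overexpression-labelled and INA 5.05 FPKM in the control-labelled libraries.

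**Figure D3:**
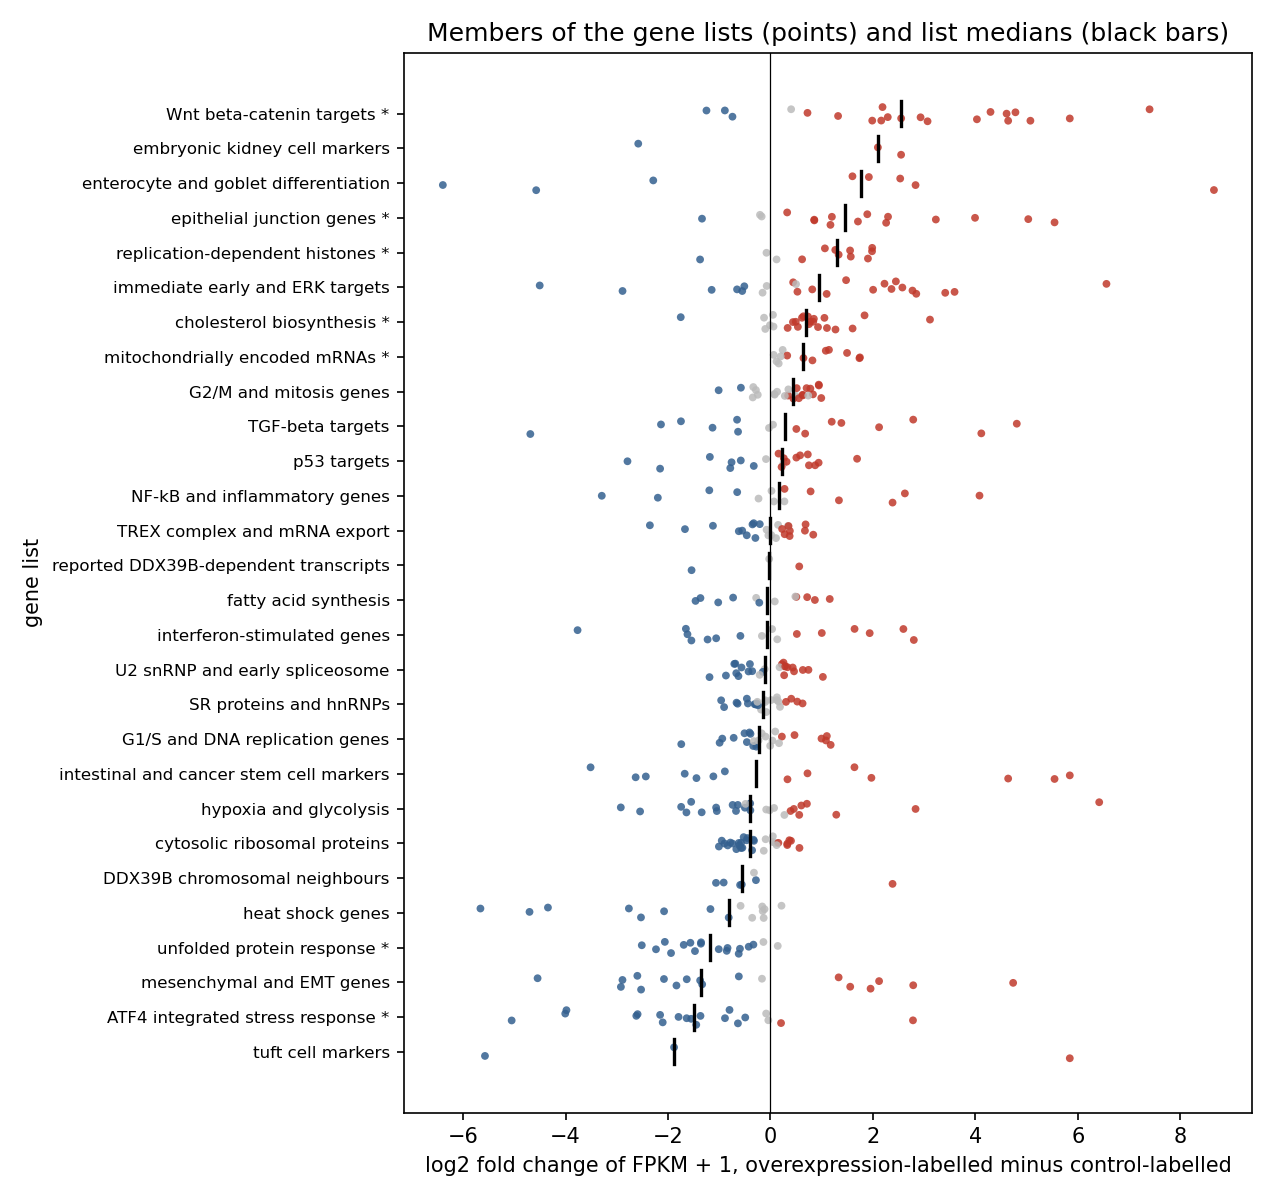
Log2 fold change of FPKM + 1 (overexpression-labelled minus control-labelled) for each tested member of the 28 gene lists with at least 3 tested members; points are genes, red for higher and blue for lower at a limma adjusted p under 0.05 and grey for the rest, and black bars are list medians. An asterisk marks the 7 lists with a camera adjusted p under 0.05 at the preset correlation, such as the Wnt targets with a median of 2.55 and the unfolded protein response with a median of -1.18; none passed with an estimated correlation, and the mitochondrial list lost its call after quantile normalization.

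In all, 7 of 28 lists passed camera with the preset correlation of 0.01, 5 higher and 2 lower, and 0 passed with the correlation estimated from the data. With limma's fry 21 passed, a test that asks whether the genes of a list move on balance in a direction and that does not compare them with other genes. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, and as the labels name no batch, any batch and the group cannot be told apart.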

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

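Of 2450 values of the 130 named genes under the alternatives, 2446 kept their direction and their side of the threshold and 4 lost the call (DDX39A under 3 scalings and HSPA6 under voom). DDX39B stayed between -1.44 and -1.25 and DCLK1 between 3.69 and 8.14 on the log2 scale, both past the threshold under every alternative run. Leaving out each library in turn gave 9794 to 11144 genes, against 10726. Array weights called more, 12517 of 13972 genes (89.6%). A fold threshold of 2 left 4358 genes, 2213 higher and 2145 lower, and that count was 7152 after rescaling to TPM, 5459 with voom and 5340 with a pseudocount of 0.1. With a mean of 5 FPKM required, 6218 genes passed (2784 higher, 3434 lower), and with no filter 15105 of 33913 (8155 higher, 6950 lower), as fewer or more genes were tested. Recomputing FPKM on the sum of reads or leaving out mitochondrial genes, both chosen after seeing the data, moved log2 fold changes by a median of 0.09 and 0.098 and called 10781 and 11248 genes, now with more higher than lower (5816 against 4965, and 6095 against 5153). The replicate block gave 10506 genes; the replicate numbers did not pair the libraries, as deviations of same-numbered libraries correlated at -0.006, -0.022 and 0.007, and no library correlated best with its own number except overexpression-labelled replicate 3. The lists past the set test went from 7 to 0 with an estimated correlation and to 21 with fry, and were 5 to 10 under the other settings. Directions of lists not past camera turned for tuft markers under fry (adjusted p 1.45e-04) and, at adjusted p values above the threshold, for interferon genes (0.103 under fry, 0.975 with protein-coding genes, 0.92 without control replicate 3, against 0.939 and 0.809 unturned without control replicate 1 or overexpression replicate 1), TREX genes (0.797 at a mean of 5 FPKM, 0.982 after quantile normalization), U2 snRNP and early spliceosome genes (0.882 at a mean of 5 FPKM, 0.848 after quantile normalization) and stem cell markers (0.974 and 0.988 without overexpression replicates 1 and 3, 0.898 unturned without control replicate 2); the cause was not tested. Planned count models were not run, as the table holds no counts.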

Other observations

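The tests of DDX39A and pseudogene reads, of swapped labels and of the genes with folds as large as that of DCLK1, the rescaling to the sum of reads, and the gene groups of the next 2 paragraphs were chosen after the results were seen. The test of windows along the chromosomes was set after the breadth of the difference was seen and before any window value was.

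Some homeobox and 11q13 genes differed widely between the groups. These groups of genes had no set test, and 76.8% of all tested genes passed the threshold, so counts near that share set none of them apart. Of 27 tested HOX genes, 18 were higher and 4 lower under the overexpression label. HOXB8 measured 138 ± 2.2 FPKM against 0.80 ± 0.20 FPKM (SD, n = 3 each), and HOXB2, HOXB3, HOXB4, HOXB5 and HOXB6 were all higher, while HOXC13, HOXC11, HOXA13 and HOXC10 were the 4 lower genes. Around CCND1 on chromosome 11, 7 of 10 tested genes were higher, CCND1 at 664 ± 7.4 against 32.9 ± 2.3 FPKM, MYEOV at 63.1 ± 0.68 against 1.00 ± 0.027 FPKM and ANO1 at 75.9 ± 2.9 against 0.023 ± 0.0062 FPKM. CTTN, within the same stretch, was lower (27.6 ± 0.78 against 44.2 ± 0.60 FPKM), and PPFIA1 and TPCN2 did not pass the threshold. The 3 tested MAGEA genes of chromosome X, MAGEA1, MAGEA3 and MAGEA6, had 0 reads in the overexpression-labelled libraries and measured 30.9 ± 2.2, 9.67 ± 0.47 and 41.4 ± 1.5 FPKM in the others, MAGEA3 and MAGEA6 being near-identical copies.

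Of 16 tested keratin genes, 11 were higher and 5 lower. KRT8 and KRT18, both among the higher genes, were abundant in both groups (681 and 609.5 against 179 and 202 FPKM). KRT7 (1.38 ± 0.24 against 81.8 ± 10.0 FPKM) and KRT17 were abundant only in the control-labelled libraries. PRF1, which encodes the pore-forming protein of cytotoxic lymphocytes, reached 171 ± 2.5 FPKM in the overexpression-labelled libraries with GZMB at 0.73 ± 0.41 FPKM, CD8A at 0.54 ± 0.13 FPKM and PTPRC and CD3D at 0 reads, and PRF1 was the only tested gene of 10 cytotoxic lymphocyte genes. Of 5 tested colon transcription factors, 3 were higher, among them CDX2 and HNF4A, and 2, GATA6 and KLF5, were lower. GATA6 had 5 reads against 555, whereas the change of KLF5 was small, at 32.1 ± 0.94 against 37.7 ± 2.0 FPKM (log2 fold change -0.22). CDKN2A measured 18.6 ± 0.24 against 67.2 ± 1.7 FPKM.

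Most tested genes, 10726 of 13972, differed between the groups. Median-ratio rescaling moved the log2 fold changes by a median of 0, so its 10701 calls cannot decide on a scaling error between libraries. A rescaling that moved the median by 0.09 called 10781 genes. Genes went both ways, 2213 higher and 2145 lower by a log2 fold change of at least 1. A common factor per library cannot alone give this, so these values argue against such an error as the whole cause. The 10 splits of the 6 libraries are too few for a share under 0.05; the labelled split gave 10726 genes and the highest of the others 0, and 1 split, the labelled one, reached that count. Cell populations with different karyotypes remain a candidate explanation, stated here as a hypothesis. Medians of log2 fold change in 288 windows of 10 Mb correlated at 0.457 with those of the window after next. The highest of 1000 shuffles of the genes was 0.21, and the SD of the medians was 0.435 against at most 0.241. The 4 windows tested in the first 50 Mb of chromosome 5 lay between -1.80 and -1.15. Chromosome 13 had a median of 0.55 but was not shifted as a whole. Its window medians went from 1.33 in the first tested window to -0.23 in the last. Domains of shared regulation longer than 10 Mb were not tested, and the overexpression named in the labels stays open as an untested biological cause. No reference profile of SW480 was compared, so which culture, if either, departs from the named line was not tested.

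DDX39B was lower in the libraries labelled as overexpressing it. The values argue against reads assigned to DDX39A or the DDX39B pseudogenes in place of DDX39B. Scaled by the FPKM denominator, the summed reads of this family were 0.512 times those of the control-labelled libraries and lower in all 3. Only reads assigned to a gene enter this sum, so reads dropped for matching several genes were not tested. A swap of the labels of the 2 groups cannot be told apart from a lower DDX39B in differing cells: its absolute log2 fold change lay at the 79.1 percentile of tested genes, so that it neither stood out nor was small. DCLK1 was 261-fold higher under the labels as given, the direction the title of the series names, and would be lower after a swap, but 318 other genes differed as much and the study itself named DCLK1, so this does not decide. A transgene that the gene model does not count was not tested, and would leave the native gene 2.70-fold lower.

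The 261-fold difference of DCLK1 may be one case of a general difference between the groups, as a hypothesis: 318 other protein-coding genes differed by at least as large a fold. A change of mRNA stability of DCLK1 was not measured by these libraries, which give levels only.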
